A study of Rattus norvegicus with 12 samples.

How the data were processed

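Total RNA from the renal cortex of 12 male Sprague-Dawley rats was measured on 1-colour Agilent arrays, 1 array per animal. Per the labels, the rats were given cisplatin, a platinum drug that cross-links DNA and harms kidney tubules, or water for 4 weeks in 2 experiments. Cisplatin was given by gavage at 3.75 mg/kg/day in one and by intravenous injection at 0.75 mg/kg/day in the other, so that route, dose and experiment changed together. Each of the 4 groups held 3 animals, which the labels call biological replicates. For the intravenous animals the dose was taken from the label of each sample, although the treatment protocol shared by all samples states 3.75 mg/kg/day.

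The authors scanned the arrays and extracted spot values with Agilent Feature Extraction 10.7, per the submitters' processing notes (10.7.1.1 per the file headers). The deposited values used here were the processed spot intensity, which per the file headers is background-subtracted within each array and not normalized between arrays, and the raw median intensity of each spot and of its local background. The software's marks for spots well above background, saturated or of uneven intensity were also used, per the file headers. The authors' deposited value table was matched to the scanner values and holds a linear ratio, the processed intensity of each probe divided by the 75th percentile of its array. Its column medians lay between 0.109 and 0.121, and 61537 probes were matched. Leaving out dim probes, the log2 ratio to the scanner values had an SD between 0.000142 and 0.00145. How the authors chose that scaling is not given in the sources used here.

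Probes carried RefSeq accessions, which were looked up in a table of the GRCr8 assembly used for names only. Of 61537 probes outside the controls, 28206 matched 1 symbol, 33331 none and 0 several. The array design refers to assembly rn4, and no positions are given. For each array the log2 processed intensity was taken minus its 75th percentile, without the 1439 control spots and without 82 single spots marked as uneven. Each spot outside the controls was taken as a probe of its own, without averaging. Of several probes of a gene (9024 genes), the one with the highest mean over all 12 arrays stood for it. A gene, or an unnamed probe, was tested if that probe was well above background on all 3 arrays of at least 1 group, which left 32215 of 45433 features, 12598 of them named genes. The 75th percentile of the signal was 969.7 to 1532 per array, 66.1% to 73.9% of probes were well above background and 0 were saturated. The number of arrays limits the precision.

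The 4 group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (8 residual degrees of freedom, moderated by a prior of 2.09), two-sided, with Benjamini-Hochberg adjustment over all features tested, and called at an adjusted p under 0.05. The contrasts were cisplatin minus water within each experiment, the difference of these effects (intravenous minus gavage), and intravenous water minus gavage water. Changes are log2 differences with their standard errors. Where a gene was not well above background on any array of the dimmer group, the fold is a bound, from the brighter group's mean to the dimmer group's mean of the higher of the probe's own signal and the lowest signal well above background on each array. For 28 gene lists with 512 genes on the array, those with 5 or more measured members (27 lists) were compared with all other genes by camera with a preset correlation of 0.01, and again with an estimated correlation. They were also tested by fry, which asks whether the members of a list change at all and does not compare them with other genes. These tests ran on the 32176 features without an omitted spot.

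The gene lists, the settings tried, the designs and the rule for the genes named in the text were fixed before the data were examined. In each main comparison the text names the 10 largest rises and 10 largest falls among genes past the test whose 3 cisplatin arrays all lay beyond the 3 water arrays and which were well above background on all 6. From each list it takes up to 4 members with the smallest p, and always Havcr1, Lcn2, Clu, Spp1, Timp1, Cdkn1a, Mdm2, Ccng1, Slc22a2 and Slc34a1. For the difference between experiments it takes the 5 largest in each direction, and for the water groups the 3 largest or, where none passed, the 5 with the smallest p. Members of a list named because 5 or fewer of it moved one way, or because they had only a bound, were chosen after their values were seen. Some genes that these rules take are not reported here.

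Slides were tested as batches. Slide 1 held the 3 gavage water arrays and gavage cisplatin replicate 1, slide 2 gavage cisplatin replicates 2 and 3 and the 3 intravenous water arrays, and slide 3 the 3 intravenous cisplatin arrays, each slide scanned at 1 time. With the slide as a fixed block the gavage effect rests on slide 1 alone, where the lone cisplatin array is assumed to vary like the other groups. In the intravenous experiment each group lay on a slide of its own, so slide and treatment cannot be told apart. A random block was fitted there (duplicateCorrelation with statmod 1.5.0, correlation -0.012) and, chosen after seeing the data, slide 2 as a term with slides 1 and 3 taken as alike. The slide 2 effect then comes only from gavage cisplatin replicate 1 against replicates 2 and 3. This widens the errors of the intravenous effect and of the difference, so a call can end without a smaller change. Under the random block the lists were tested by cameraPR on the moderated t of the fit, in place of camera, so their adjusted p also changed with the test. A scaling on 7 of the 10 E1A spike-in probes was also chosen after seeing the data. Other settings tried were normexp background correction with an offset of 50 on the median spot signal (the deposited files held no mean signal), quantile normalization, no filter, a filter on all 12 arrays, the mean of all probes of a gene, the uneven spots kept, the deposited ratios, fits on 6 arrays, array weights, a trended robust prior, the replicate number as a block, stricter thresholds and each array left out in turn.

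The fit was tested on simulated data with 32176 features, of which 50 each were changed by a log2 of 0.5, 1, 2 or 4. In the simulated gavage comparison 7, 40, 48 and 49 of the 50 were called, with 8 of 31976 unchanged features. In the simulated intravenous comparison 8, 38, 47 and 48 of the 50 were called, with 2 of 31976 unchanged features. A planted list was called in both and 0 of 26 other lists. Simulated features varied independently and without slide effects, so this does not show how the list test behaves with correlated genes. Names and tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.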

Results

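Gene expression was measured in the renal cortex of rats after 4 weeks of cisplatin or water. It was given by gavage (3.75 mg/kg/day) or by intravenous injection (0.75 mg/kg/day), with 3 animals and 3 arrays in each of the 4 groups. Arrays of the same group correlated at r = 0.981 to 0.993 across probes and arrays of different groups at 0.910 to 0.992. The first principal component held 75.7% of the variance and set the 6 water arrays (-103 to -97.1) apart from the 6 cisplatin arrays (52.6 to 134). The cisplatin arrays were brighter, with a 75th percentile of 1439 to 1532 against 969.7 to 1019.6 in the gavage experiment and 1387 to 1407 against 1008 to 1055 in the intravenous experiment. The median SD per gene was 0.126 and 0.129 in the water groups and 0.178 and 0.185 in the cisplatin groups (log2, n = 3 each).

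The gavage comparison asked which cortical transcripts differ after 4 weeks of oral cisplatin. Transcripts of tubule injury, p53 targets, matrix and cell division rose, while those of tubule transport, mitochondrial metabolism, the distal nephron and red cells fell. With an estimated correlation 0 of the 14 list calls in this comparison held (lowest adjusted p = 0.0513). Havcr1, which encodes the injury protein KIM-1 of the proximal tubule, rose by 10.95 ± 0.36 (log2 ± SE, n = 3 per group, 1983-fold, limma adjusted p = 4.25e-08). Lcn2, a siderophore-binding lipocalin, rose by 7.84 ± 0.61 (229-fold). The activin antagonist Fst rose by 7.71 ± 0.16 (209-fold), the drug efflux pump Abcb1b by 7.54 ± 0.23 (186-fold), the cytokine Il24 by 7.75 ± 0.31 and the protease inhibitor Serpina3n by 9.15 ± 1.24. Ltbp2, Gpnmb and A2m rose by 6.42, 6.29 and 5.96. Umod, the uromodulin gene of the thick ascending limb, changed by -8.95 ± 1.39, Egf by -6.48 ± 0.38, the secreted phosphoprotein Spp2 by -7.62 ± 1.35 and the proton pump Atp12a by -6.95 ± 0.82. The globin genes Hbe2, Hbb-b1, Hba-a3, Hbb-bs, Hbb and Hba-a1 changed by -8.95, -8.65, -8.59, -8.54, -8.45 and -6.57, values that are uncertain singly because probes of paralogs can share transcripts. In each of these genes, as the rule that chose them required, all 3 cisplatin arrays lay beyond all 3 water arrays. Their adjusted p lay between 3.51e-09 (Fst) and 7.57e-04 (Spp2).

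With the slide as a block, which equals slide 1 alone, these rises lay between 5.19 (A2m) and 11.16 (Havcr1) and these falls between -9.79 (Umod) and -6.72 (Egf). Single arrays moved some folds by over 1.5 times. Without gavage water replicate 2 the change was 10.25 for Serpina3n (8.49 without water replicate 3) and 6.93 for Lcn2. Without gavage cisplatin replicate 2 it was -9.71 for Umod, -8.41 for Spp2, -9.57 for Hbe2, -9.31 for Hbb-b1, -9.17 for Hbb-bs and -9.14 for Hbb. Without cisplatin replicate 3 it was -6.43 for Spp2, -8.05 for Hbb-b1 and -7.85 for Hbb.

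Of the 24 kidney injury markers measured, 21 rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone. Clu, a secreted chaperone, rose by 3.72 ± 0.12, Spp1, which encodes osteopontin, by 4.81 ± 0.19. The metalloproteinase inhibitor Timp1 rose by 4.33 ± 0.18 and the fibrinogen chain Fgb by 5.32 ± 0.17, while the trefoil peptide Tff3 changed by -4.13 ± 0.86 (-3.51 without cisplatin replicate 3, -3.54 with the slide as a block). The list median was 3.60 (camera adjusted p = 6.63e-11, adjusted p = 0.0513 with an estimated correlation), and 3.61 with the slide as a block. Of 24 p53 target genes, 17 rose, 2 fell and 5 did not pass (17 and 3 adjusted over the list alone). Phlda3, an inhibitor of AKT, rose by 5.33 ± 0.15, the death receptor Fas by 4.21 ± 0.13, Bbc3, a pro-apoptotic BCL2 family member, by 3.65 ± 0.14. The p53 ubiquitin ligase Mdm2 rose by 3.18 ± 0.13 and the cyclin Ccng1 by 3.17 ± 0.13, and Rrm2b and Xpc changed by -0.87 and -0.51. Neither of these falls passed with spike-in scaling (-0.21 and 0.16), nor did Rrm2b with the slide as a block (-0.72). Their median was 2.05 (adjusted p = 8.75e-07, adjusted p = 0.186 with an estimated correlation), 2.05 with the slide as a block and 1.57 with Pmaip1, not well above background in water, at its bound. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, gave -0.19 ± 0.08 (adjusted p = 0.0564) with the probe that stood for it, a value that was -0.35 with the slide as a block (adjusted p = 0.0102), -0.25 without gavage cisplatin replicate 2 (adjusted p = 0.0312) and turned to 0.47 with spike-in scaling, and 6.06 ± 0.14 and 5.59 ± 0.17 with its other two probes.

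Transcripts of the proximal tubule fell together. Of 36 transporters measured, 32 fell, 2 rose and 2 did not pass. The organic cation transporter Slc22a2, which takes up cisplatin, changed by -5.25 ± 0.84, the phosphate transporter Slc34a1 by -4.97 ± 0.83. The amino acid transporter Slc6a19 changed by -3.84 ± 0.30, the sodium-hydrogen exchanger Slc9a3 by -3.55 ± 0.29, the dicarboxylate transporter Slc13a3 by -2.62 ± 0.20 and the efflux transporter Slc47a1 by -2.08 ± 0.18. The glucose transporter Slc2a2 and the efflux pump Abcc2 rose by 0.60 ± 0.13 and 2.77 ± 0.44. The transporters had a median of -2.64 (adjusted p = 1.56e-08, adjusted p = 0.287 with an estimated correlation; -2.42 with the slide as a block). Without gavage cisplatin replicate 3, Slc22a2 was -4.58, Slc34a1 -4.14 and Abcc2 3.42, and without replicate 2, Slc34a1 was -5.69. Of 27 genes of amino acid and sugar metabolism, 26 fell and 1 did not pass. Among those that fell were the betaine methyltransferase Bhmt (-3.66 ± 0.27), Glyatl2 (-2.73 ± 0.21), pyruvate carboxylase Pc (-3.40 ± 0.31) and Hao2 (-1.78 ± 0.17). The median of this list was -3.40 (adjusted p = 9.32e-10, adjusted p = 0.287 with an estimated correlation) and -3.25 with the slide as a block. All 26 genes of fatty acid oxidation and all 22 of oxidative phosphorylation fell. The dehydrogenase Hadh changed by -2.58 ± 0.12, the electron carrier Etfa by -1.44 ± 0.07 and the carnitine palmitoyltransferase Cpt2 by -1.31 ± 0.08. The respiratory chain subunits Sdhd, Ndufa9, Uqcrfs1 and Atp5f1c changed by -1.28, -1.12, -1.30 and -1.41. Medians were -1.79 for fatty acid oxidation (adjusted p = 1.27e-11, adjusted p = 0.243 with an estimated correlation) and -1.21 for oxidative phosphorylation (adjusted p = 6.02e-11, adjusted p = 0.243 with an estimated correlation), and -1.73 and -1.17 with the slide as a block. Counts in these lists were the same adjusted over the list alone.

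Further along the nephron, 12 of 14 markers of the thick ascending limb and distal tubule fell and 2 did not pass. Besides Umod and Egf these were among others the kallikrein Klk1 (-3.81 ± 0.23), the potassium channel Kcnj1 (-2.35 ± 0.21) and the calcium-binding Calb1 (-2.36 ± 0.25). Their median was -2.34 (adjusted p = 2.76e-05, adjusted p = 0.287 with an estimated correlation), -2.21 with the slide as a block and -2.27 with Kcnj10, not well above background with cisplatin, at its bound. Of 16 collecting duct markers 10 fell, 1 rose and 5 did not pass. The proton pump subunit Atp6v1b1, the vasopressin receptor Avpr2 and the steroid dehydrogenase Hsd11b2 changed by -1.45, -1.38 and -1.39, and the water channel Aqp4 rose by 4.17 ± 0.34. The collecting duct median was -0.56 (adjusted p = 0.0213, adjusted p = 0.287 with an estimated correlation). It was 0.11 with spike-in scaling, where the list still passed as lower than other genes (camera adjusted p = 0.00532). Its call ended with the slide as a block (-0.50, adjusted p = 0.115), with normexp (adjusted p = 0.0989) and with quantile normalization (adjusted p = 0.0624). Podocyte markers (1 rose, 6 fell, 5 did not pass; median -0.47, adjusted p = 0.133, but 0.20 with spike-in scaling) and endothelial markers (1 rose, 4 fell, 7 did not pass; -0.14, adjusted p = 0.362, but 0.52 with spike-in scaling) did not shift as lists by camera. By fry both lists passed (adjusted p = 2.11e-04 and 0.00980). The endothelial receptor Kdr changed by -1.10 ± 0.10, and the podocyte gene Nphs1 by -0.54, which turned to 0.13 with spike-in scaling. With the slide as a block the medians of these 2 lists were -0.60 and -0.15. Of 10 renal endocrine genes 7 fell, 2 rose and 1 did not pass (median -1.32, adjusted p = 0.0501). With the slide as a random block, where the list test differed too, this list passed (-1.31, cameraPR adjusted p = 0.0355). So it did with spike-in scaling (-0.65, adjusted p = 2.32e-04) and without any 1 of 6 of the 12 arrays (-1.49 to -1.22), but not with the slide as a fixed block (-1.51, adjusted p = 0.0708). It also passed with the mean of all probes (-2.02, adjusted p = 0.0436), array weights (0.0365) and the 6 gavage arrays alone (0.0392). With the uneven spots kept (0.0499), with the deposited ratios (0.04996) and by fry (8.94e-06) it passed as well. The calcium-sensing receptor Casr changed by -4.79 ± 0.35 and the FGF23 co-receptor Kl by -2.56 ± 0.32. Counts were the same adjusted over the list alone.

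All 28 genes of extracellular matrix and fibroblasts rose, also adjusted over the list alone. Among them were the collagen Col18a1 (2.33 ± 0.10), fibronectin Fn1 (3.33 ± 0.17), the cytokine Tgfb1 (1.52 ± 0.10) and the proteoglycan Bgn (1.58 ± 0.12). The matrix median was 2.07 (adjusted p = 6.02e-11, adjusted p = 0.275 with an estimated correlation), 2.18 with the slide as a block and 1.92 with Lum at its bound. Of 16 macrophage markers 13 rose and 3 did not pass, in the same numbers adjusted over the list alone. The mannose receptor Mrc1 rose by 3.46 ± 0.37, the lipopolysaccharide co-receptor Cd14 by 2.17 ± 0.25, and Cd68 by 1.71 ± 0.23. The scavenger receptor Cd163 rose at least 34.0-fold (a fitted 6.92, 7.80 and 6.23 without cisplatin replicates 2 and 3). Macrophage markers had a median of 1.19 (adjusted p = 2.05e-04, adjusted p = 0.287 with an estimated correlation; 1.27 with the slide as a block). Of 18 lymphocyte markers 2 rose, Ltb (0.52 ± 0.18) and Ptprc (0.61 ± 0.24), and 0 adjusted over the list alone (median 0.24, adjusted p = 0.543). The call of Ltb ended without 1 of 3 arrays (0.35 without cisplatin replicate 1), and that of Ptprc without any 1 of 8 arrays (0.51 to 0.64) and with the slide as a block (0.81). With the replicate number as a block neither passed (limma adjusted p = 0.0513 and 0.0609). Of 22 chemokines and NF-kB targets 13 rose, 4 fell and 5 did not pass, also adjusted over the list alone. The adhesion molecule Icam1 rose by 1.58 ± 0.10, the macrophage growth factor Csf1 by 2.31 ± 0.15 and the chemokine Cxcl1 by 4.64 ± 0.43, and Ccl4, Ccl5, Cx3cl1 and Il34 changed by -1.23, -0.99, -0.77 and -0.52. With spike-in scaling none of these 4 falls passed, Il34 being 0.15, and with the slide as a block Ccl4, Ccl5 and Il34 did not (-0.95, -0.71 and -0.48). Il34 did not pass with quantile normalization either (-0.28). The call of Ccl5 also ended without gavage water replicate 1 (-0.76), without cisplatin replicate 2 (-1.04) or 3 (-0.80) and with the replicate number as a block (-0.99). Their median was 0.72 (adjusted p = 0.0342, adjusted p = 0.372 with an estimated correlation), 0.93 with the slide as a block. This call ended without gavage water replicate 3 (0.67), without intravenous cisplatin replicate 1 (0.72) and with the 6 gavage arrays alone (adjusted p = 0.0547). It also ended with spike-in scaling (adjusted p = 0.306), at a larger median (1.38). Of 21 interferon response genes 9 rose, 1 (Mx2, -0.94 ± 0.08) fell and 11 did not pass (median 0.71, adjusted p = 0.0768). The interferon list passed with normexp (0.54, adjusted p = 0.0131), with the 6 gavage arrays alone (adjusted p = 0.0366), and without gavage cisplatin replicate 2 (0.84), gavage water replicate 2 (0.95) or intravenous water replicate 3 (0.71). It also passed without a filter (adjusted p = 0.0173), with the mean of all probes (0.69, adjusted p = 0.0468) and by fry (adjusted p = 0.0466).

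Of 29 cell cycle genes 26 rose, 1 fell and 2 did not pass (27 and 1 adjusted over the list alone). The thymidylate synthase Tyms rose by 1.62 ± 0.12, and the replication licensing factors Mcm2 and Mcm3 by 1.36 ± 0.10 and 2.62 ± 0.24. The cyclin Ccne1 rose by 3.33 ± 0.32, while the spindle kinesin Kif11 changed by -1.39 ± 0.42, a call that ended without cisplatin replicate 3 (-1.03), with the slide as a block (-1.25) and with spike-in scaling (-0.72). The cell cycle list had a median of 1.71 (adjusted p = 8.17e-08, adjusted p = 0.304 with an estimated correlation) and 1.75 with the slide as a block. Of 15 immediate early genes 11 rose, 1 fell and 3 did not pass, also adjusted over the list alone. The transcription factors Fosl1 and Egr2, not well above background in water, rose at least 143-fold and at least 32.5-fold, Egr1 rose by 3.22 ± 0.18 and Fos by 3.37 ± 0.20, and Fosb changed by -0.61 (0.053 with spike-in scaling). The immediate early median was 1.60 (adjusted p = 6.92e-05, adjusted p = 0.243 with an estimated correlation; 1.52 with the slide as a block). Of 6 erythrocyte markers 5 fell (6 adjusted over the list alone). The haem synthesis enzyme Alas2 changed by -7.21 ± 0.40 (well above background on 1 of 3 cisplatin arrays) and the anion exchanger Slc4a1, also made by kidney intercalated cells, by -2.40 ± 0.40. The erythrocyte median was -4.48 (adjusted p = 0.00159, adjusted p = 0.243 with an estimated correlation; -4.45 with the slide as a block).

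The other lists did not shift as a whole by camera, and their members went both ways, those not counted here not passing. By fry 5 of them passed: DNA repair (adjusted p = 3.55e-04), Nrf2 (0.00988), metal and platinum handling (1.05e-04), stress response (4.60e-04) and adipocyte genes (0.0109). Of 17 genes of DNA crosslink and excision repair 7 rose and 3 fell (median 0.11, adjusted p = 0.281). Brca2 rose by 1.62 ± 0.18 and Ercc1 by 0.98 ± 0.14, and Xpa, Fancc and Fancl changed by -0.46, -0.68 and -0.44. With spike-in scaling none of these 3 falls passed (0.21, -0.018 and 0.23), nor did Xpa (-0.35) and Fancl (-0.20) with the slide as a block. The call of Fancl also ended without gavage water replicate 1 (-0.44) or 3 (-0.31) and without cisplatin replicate 2 (-0.46) or 3 (-0.30). So it did without a filter and with the 6 gavage arrays alone (-0.44 each). Of 20 Nrf2 antioxidant genes 8 rose and 8 fell (median 0.08 and mean 0.33 against a test that pointed down, adjusted p = 0.926). Among them the sulfiredoxin Srxn1 rose by 3.51 ± 0.32 and the glutathione transferase Gsta3 changed by -2.50 ± 0.23. Of 13 genes of metal and platinum handling 2 rose and 7 fell (median -0.40, adjusted p = 0.147, but 0.26 with spike-in scaling), including the copper transporter Slc31a2 (2.24 ± 0.25) and the glutamyltransferase Ggt1 (-1.90 ± 0.22). Of 15 genes of the unfolded protein and integrated stress response 6 rose and 3 fell (median 0.02, adjusted p = 0.351). Asparagine synthetase Asns rose by 2.50 ± 0.12 and the stress factors Atf3 and Ddit3 by 4.01 ± 0.28 and 1.36 ± 0.15, and Herpud1, Dnajb9 and Hspa5 changed by -1.41, -0.66 and -0.49. With spike-in scaling Dnajb9 was 0.0038 and Hspa5 0.18, and the call of Hspa5 ended with the slide as a block (-0.37) and without gavage water replicate 2 (-0.41) or 3 (-0.37) or cisplatin replicate 2 (-0.40). It also ended with quantile normalization (-0.20) and with the 6 gavage arrays alone (-0.49). Of 21 cholesterol synthesis genes 5 rose and 7 fell (median -0.04, adjusted p = 0.747, but 0.63 with spike-in scaling). Of 14 circadian genes 3 rose and 4 fell (1 and 4 adjusted over the list alone; median 0.11 and mean 0.15 against a test that pointed down, adjusted p = 0.926, and a median of -0.04 with the slide as a block). Npas2 changed by -2.00 ± 0.16 and Bmal1 by -1.23 ± 0.17. Of 7 adipocyte markers 3 rose and 2 fell (4 and 2 adjusted over the list alone; median 0.54, adjusted p = 0.390, 0.89 with the slide as a block). The adipsin gene Cfd rose by 2.96 ± 0.38 and the fatty acid carrier Fabp4 by 2.60 ± 0.44. Of 12 housekeeping genes 2 rose and 3 fell (median -0.0021 and mean 0.02, adjusted p = 0.951), but the median was 0.66 with spike-in scaling, where Gapdh turned from -0.44 to 0.22 and Ppia from -0.34 to 0.33. Counts given once were the same adjusted over the list alone.

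In all, 9494 features were higher and 9717 lower with gavage cisplatin, of 32215 tested (named genes 3808 and 4117), 4306 and 3757 of them by at least 2-fold. The 3 cisplatin arrays lay beyond the 3 water arrays in 67.2% of features, where chance gives 10%. With the slide as a block 7041 were higher and 8103 lower, and 14122 calls were shared in the same direction. Among 125 genes named by rule 120 kept their direction and side of the threshold there, Cidec (-2.37 to -2.10), Clock (-0.61 to -0.27), Lipe (-0.96 to -0.70) and Ptprc lost their call, and the probe that stood for Cdkn1a, not called before, was called lower (-0.19 to -0.35). Scaled on spike-in probes, the median of all features moved by 0.67, and 86.6% of calls in place of 49.4% were higher (20049 higher, 3103 lower). All changes given here are relative to the 75th percentile of each array. With normexp that median was -0.13 and 38.9% of calls were higher.

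**Figure D1:**
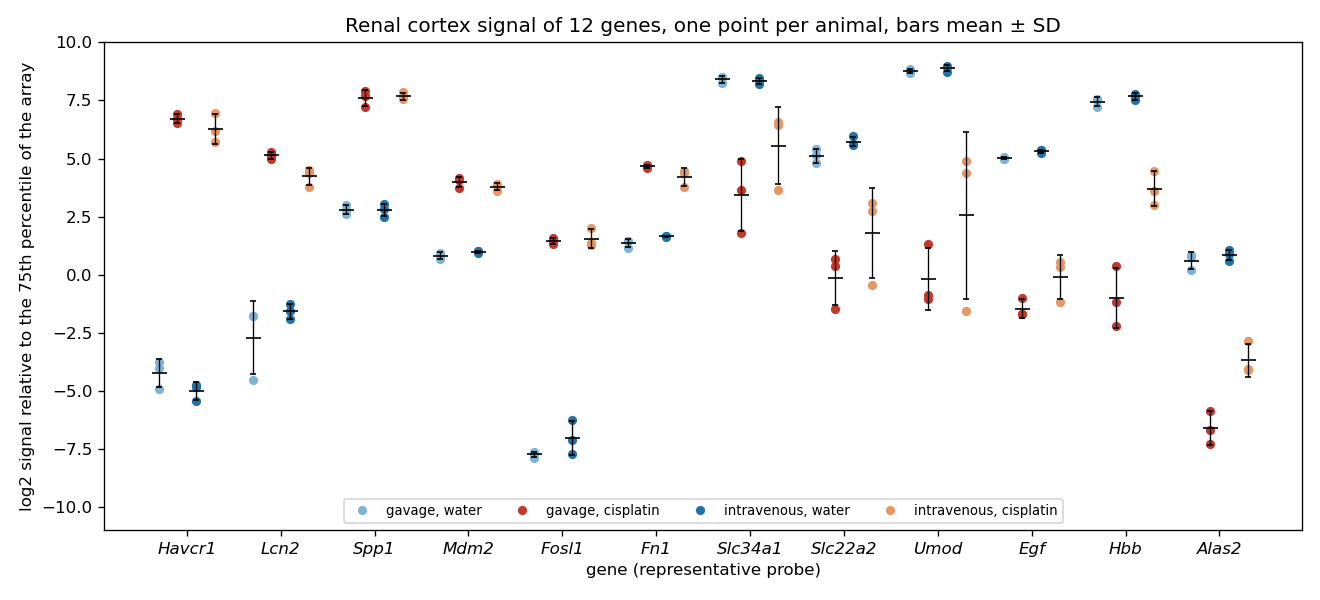
Signal of 12 genes in each animal, as log2 relative to the array's 75th percentile (vertical axis), for the 4 groups (1 point per animal, bars mean ± SD, n = 3). Havcr1 stood at -4.24 with gavage water and 6.72 with gavage cisplatin, and Umod changed by -8.95 by gavage and -6.33 by injection.

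The intravenous comparison asked the same of cisplatin injected at 0.75 mg/kg/day. Transcripts of tubule injury, p53 targets, matrix, cell division and chemokines rose, while those of tubule transport, mitochondrial metabolism, the distal tubule and red cells fell. With an estimated correlation 1 of the 16 list calls in this comparison held, that of the injury markers (adjusted p = 0.0332). Havcr1 rose by 11.28 ± 0.36 (2486-fold, adjusted p = 3.99e-08, n = 3 per group), with the water arrays well above background on 2 of 3. The drug efflux pump Abcb1b rose by 7.43 ± 0.23 (173-fold), the activin antagonist Fst by 6.63 ± 0.16 (99.1-fold), the adrenergic receptor Adra1d by 5.82 ± 0.20, Lcn2 by 5.80 ± 0.61 and Serpina3n by 7.03 ± 1.24. Gpnmb, A2m, Phlda3 and Fgb rose by 5.78, 5.58, 5.28 and 5.28. Umod changed by -6.33 ± 1.39, Egf by -5.41 ± 0.38, the phosphatase inhibitor Ppp1r1a by -4.75 ± 0.52, Atp12a by -4.63 ± 0.82 and Spp2 by -4.59 ± 1.35. Nat8f1 changed by -4.53 ± 0.87, the haem synthesis enzyme Alas2 by -4.53 ± 0.40 and regucalcin Rgn by -4.50 ± 0.56. The histamine methyltransferase Hnmt changed by -4.47 ± 0.77 and the globin Hbb-bs, which can share probes with paralogs, by -4.43 ± 0.54. In each of these genes all 3 cisplatin arrays lay beyond the 3 water arrays, which the rule that chose them required of all but Havcr1. Their adjusted p lay between 1.40e-08 (Fst) and 0.0143 (Spp2).

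Intravenous cisplatin replicate 1 lay farther from the water arrays on the first principal component (113.6) than the other two (73.2 and 52.6). This array correlated more with the gavage cisplatin arrays (r = 0.990 to 0.992) than with the others of its own group (0.982 and 0.981). Without it the change was -4.27 for Umod, -2.83 for Spp2, -3.49 for Atp12a, -3.23 for Nat8f1, -3.70 for Rgn, -3.33 for Hnmt, -4.13 for Ppp1r1a and 8.32 for Serpina3n. Without cisplatin replicate 2 it was -7.23 for Umod, -5.42 for Spp2 and -5.09 for Hnmt. Without replicate 3 it was -7.49 for Umod, -5.52 for Spp2, -5.31 for Atp12a, -5.30 for Nat8f1 and 6.15 for Serpina3n, which was also 6.15 without water replicate 1. With slide 2 as a term, a setting that assumes slides 1 and 3 to be alike, Umod (-5.06), Spp2 (-5.79), Atp12a (-4.37), Nat8f1 (-4.42) and Serpina3n (6.04) did not pass. This setting has wider errors, and of these genes only Spp2 lay farther from no change than in the main fit (-4.59).

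Of 24 kidney injury markers 21 rose, 1 (Tff3, -3.50 ± 0.86) fell and 2 did not pass, also adjusted over the list alone. Tff3 was -2.30, -4.11 and -4.09 without cisplatin replicates 1, 2 and 3, and did not pass with slide 2 as a term (-4.38). Clu rose by 3.995 ± 0.12, Spp1 by 4.89 ± 0.19 and Timp1 by 4.07 ± 0.18. The median was 3.35 (adjusted p = 6.99e-12), a call that held with an estimated correlation (adjusted p = 0.0332), and it was 3.37 with slide 2 as a term. Of 24 p53 targets 17 rose, 1 fell and 6 did not pass (19 and 1 adjusted over the list alone). Fas rose by 4.15 ± 0.13, Bbc3 by 3.39 ± 0.14, Ccng1 by 3.02 ± 0.13 and Mdm2 by 2.79 ± 0.13. Their median was 1.85 (adjusted p = 4.95e-09, adjusted p = 0.0755 with an estimated correlation), 1.86 with slide 2 as a term and 1.33 with Pmaip1 at its bound. Cdkn1a fell with the probe that stood for it (-0.59 ± 0.08, adjusted p = 1.69e-04), with -0.36 for slide 2 as a term and -0.03, not past the test, for spike-in scaling. Its other two probes rose by 5.87 ± 0.14 and 5.49 ± 0.17.

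Of 36 proximal tubule transporters 28 fell, 2 rose and 6 did not pass (30 and 2 adjusted over the list alone). The fructose transporter Slc2a5 changed by -2.54 ± 0.27, Slc6a19 by -2.51 ± 0.30, Slc9a3 by -2.25 ± 0.29, Slc22a2 by -3.93 ± 0.84 and Slc34a1 by -2.80 ± 0.83. Slc2a2 and Abcc2 rose by 1.05 ± 0.13 and 3.09 ± 0.44. Slc22a2 was -2.81 and Slc34a1 -1.85 without cisplatin replicate 1, Slc22a2 was -4.59 without replicate 3, and with slide 2 as a term neither passed (-4.69 and -3.10), nor did Abcc2 (2.37). The transporter median was -1.56 (adjusted p = 7.26e-05, adjusted p = 0.440 with an estimated correlation; -1.77 with slide 2 as a term). Of 27 genes of amino acid and sugar metabolism 25 fell and 2 did not pass, also adjusted over the list alone. Bhmt changed by -2.36 ± 0.27, Glyatl2 by -1.73 ± 0.21 and Pc by -2.27 ± 0.31. The metabolism median was -2.23 (adjusted p = 5.72e-06, adjusted p = 0.440 with an estimated correlation) and -2.06 with slide 2 as a term, and it moved to -1.59 without intravenous cisplatin replicate 1. Of 26 fatty acid oxidation genes 25 fell and 1 did not pass, and of 22 oxidative phosphorylation genes 21 fell and 1 did not pass (26 and 22 adjusted over the list alone). Hadh changed by -1.94 ± 0.12, Etfa by -0.95 ± 0.07, Etfdh by -1.64 ± 0.16, Ndufa9 by -0.96 ± 0.07 and Sdhc by -1.17 ± 0.09. Their medians were -1.32 (adjusted p = 4.95e-09, adjusted p = 0.263 with an estimated correlation; -1.21 with slide 2 as a term) and -0.86 (adjusted p = 8.39e-09, adjusted p = 0.263 with an estimated correlation; -0.95).

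Of 14 thick ascending limb and distal tubule markers 12 fell and 2 did not pass. Klk1 changed by -2.64 ± 0.23, the sodium-chloride cotransporter Slc12a3 by -2.44 ± 0.24 and Kcnj1 by -2.16 ± 0.21. The distal tubule median was -1.95 (adjusted p = 1.89e-04, adjusted p = 0.371 with an estimated correlation) and -2.21 with slide 2 as a term. Collecting duct markers (2 rose, 9 fell, 5 did not pass) had a median of -0.48 (adjusted p = 0.109), -0.75 with slide 2 as a term (adjusted p = 0.0156) and 0.08 with spike-in scaling. Atp6v1b1 changed by -1.35 ± 0.12, and Aqp4 rose by 2.33 ± 0.34 (1.94 with slide 2 as a term, not past the test). Podocyte markers (1 rose, 5 fell, 6 did not pass) and endothelial markers (2 rose, 4 fell, 6 did not pass) had medians of -0.51 (adjusted p = 0.435) and -0.22 (adjusted p = 0.552). With spike-in scaling these were 0.05 and 0.34, and with slide 2 as a term -0.38 and -0.41. The falls of the podocyte genes Podxl and Clic5 (-0.55 and -0.53) and of the endothelial genes Ehd3 and Tie1 (-0.46 and -0.38) turned to positive values not past the test with spike-in scaling. These 4 calls also ended with slide 2 as a term. The endothelial Kdr changed by -0.92 ± 0.10 and the podocyte cyclin-dependent kinase inhibitor Cdkn1c rose by 1.14 ± 0.15 (0.71 with slide 2 as a term, not past the test). Of 10 renal endocrine genes 8 fell and 2 rose (median -1.63, adjusted p = 0.0632). This list passed with slide 2 as a term (-1.54, adjusted p = 0.0324), with spike-in scaling (-1.07, adjusted p = 8.72e-04) and without intravenous cisplatin replicate 3 (-1.55, adjusted p = 0.0437). Casr changed by -3.69 ± 0.35. Counts were the same adjusted over the list alone.

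Of 28 matrix and fibroblast genes 25 rose and 3 did not pass. Col18a1 rose by 2.00 ± 0.10, Fn1 by 2.56 ± 0.17, Tgfb1 by 1.47 ± 0.10 and the gelatinase Mmp2 by 3.03 ± 0.30. The matrix median was 1.51 (adjusted p = 4.29e-10, adjusted p = 0.263 with an estimated correlation) and 1.52 with slide 2 as a term. Of 16 macrophage markers 7 rose and 9 did not pass. The scavenger receptor Msr1 rose by 2.41 ± 0.26, Cd14 by 2.13 ± 0.25 and Mrc1 by 2.64 ± 0.37. The macrophage median was 0.61 (adjusted p = 0.00119, adjusted p = 0.389 with an estimated correlation) and 0.53 with slide 2 as a term. Of 18 lymphocyte markers 11 rose and 7 did not pass. The lymphocyte median was 1.19 (adjusted p = 0.00276, adjusted p = 0.465 with an estimated correlation) and 0.96 with slide 2 as a term. Spike-in scaling ended the lymphocyte call (adjusted p = 0.0731) at a larger median (1.75). The cytokine Ltb rose by 1.13 ± 0.18, the leukocyte phosphatase Ptprc by 1.38 ± 0.24, the actin regulator Coro1a by 1.33 ± 0.29 and Cd5 at least 3.17-fold. With slide 2 as a term these were 0.63, 1.08, 0.90 and 1.97 and none of the 4 passed. The fitted 2.58 of Cd5 was 3.26 without cisplatin replicate 1. Of 22 chemokines and NF-kB targets 14 rose, 1 fell (Cx3cl1, -0.44) and 7 did not pass. The call of Cx3cl1 ended without any 1 of 5 of the 6 intravenous arrays (-0.48 to -0.29) and held without water replicate 3. It also ended with slide 2 as a term (-0.39), spike-in scaling (0.12), quantile normalization (-0.22) and the mean of all probes (-0.34). Without a filter, and with the 6 intravenous arrays alone, it ended as well (-0.44 each). Icam1 rose by 1.87 ± 0.10, Csf1 by 2.26 ± 0.15, Cxcl1 by 3.96 ± 0.43 and the chemokine Ccl7 by 2.46 ± 0.27. The chemokine median was 1.11 (adjusted p = 7.26e-05, adjusted p = 0.263 with an estimated correlation) and 0.95 with slide 2 as a term. Of 21 interferon response genes 13 rose, 1 fell (Mx2, -0.996 ± 0.08, not past the test with the mean of its probes) and 7 did not pass. Irf1 rose by 1.65 ± 0.26 and Ifitm3 by 1.00 ± 0.15. The interferon median was 0.74 (adjusted p = 0.00326, adjusted p = 0.440 with an estimated correlation) and 0.82 with slide 2 as a term. Spike-in scaling ended the interferon call (adjusted p = 0.0643), although the median was then larger (1.30). Counts were the same adjusted over the list alone.

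Of 29 cell cycle genes 27 rose and 2 did not pass. Tyms rose by 2.01 ± 0.12, Mcm2 by 1.34 ± 0.10, Ccne1 by 3.11 ± 0.32 and Mcm7 by 0.96 ± 0.10. The cell cycle median was 1.89 (adjusted p = 2.01e-09, adjusted p = 0.331 with an estimated correlation) and 1.81 with slide 2 as a term. Of 17 DNA repair genes 8 rose, 1 fell (Fancc, -0.49, but 0.070 with spike-in scaling) and 8 did not pass. Brca2 rose by 1.18 ± 0.18. The repair median was 0.32 (adjusted p = 0.0181, adjusted p = 0.263 with an estimated correlation). Its call ended with slide 2 as a term (0.23, adjusted p = 0.106). With the slide as a random block it ended at the same median (0.32, cameraPR adjusted p = 0.0503), where the list test differed too. Of 15 immediate early genes 10 rose, 2 fell (Fosb and Egr3, -1.001 and -0.54) and 3 did not pass. The call of Egr3 ended without water replicate 1 (-0.43) or 3 (-0.54), without cisplatin replicate 1 (-0.44) or 2 (-0.48), with slide 2 as a term (-0.47) and with spike-in scaling (0.024). Fosl1 rose at least 137-fold and Egr2 at least 16.5-fold, and Egr1 and Fos by 3.53 ± 0.18 and 3.22 ± 0.20. The immediate early median was 1.18 (adjusted p = 1.18e-04, adjusted p = 0.263 with an estimated correlation) and 1.34 with slide 2 as a term. All 6 erythrocyte markers fell. Hba-a1 changed by -3.93 ± 0.35, Hbb by -3.98 ± 0.56 and the haemoglobin chaperone Ahsp by -2.44 ± 0.44 (not past the test with slide 2 as a term, -2.55). The erythrocyte median was -3.18 (adjusted p = 0.00317, adjusted p = 0.263 with an estimated correlation) and -2.84 with slide 2 as a term. Counts were the same adjusted over the list alone.

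The remaining lists did not shift as a whole by camera, and members not counted here did not pass. By fry 5 of them passed: metal and platinum handling (adjusted p = 1.70e-04), stress response (0.00210), adipocyte (0.00616), circadian (0.0397) and housekeeping genes (0.0380). Of 20 Nrf2 antioxidant genes 10 rose and 9 fell (median 0.17, adjusted p = 0.789), Srxn1 by 3.38 ± 0.32 and the growth inhibitor Osgin1 by -2.25 ± 0.18. Of 13 genes of metal and platinum handling 2 rose and 6 fell (median -0.30, adjusted p = 0.287, but 0.26 with spike-in scaling), the copper and cisplatin importer Slc31a1 by -2.64 ± 0.31 (-1.33 with slide 2 as a term). Of 15 stress response genes 6 rose and 3 fell (median 0.03, adjusted p = 0.240, -0.02 with slide 2 as a term). Asns rose by 2.15 ± 0.12 and Atf3 by 3.54 ± 0.28, and Herpud1, Dnajb9 and Chac1 changed by -1.57, -0.45 and -0.35. Dnajb9 and Chac1 did not pass with slide 2 as a term (-0.43 and -0.019) or spike-in scaling (0.11 and 0.21). Chac1 turned to 1.49 with the mean of its probes, and its call ended without water replicate 2 (-0.34) or 3 (-0.32) or cisplatin replicate 1 (-0.29). Of 21 cholesterol synthesis genes 5 rose and 6 fell (5 and 8 adjusted over the list alone), with a median of -0.00097 and a mean of -0.05 against a test that pointed up (adjusted p = 0.924) and 0.56 with spike-in scaling. Of 14 circadian genes 3 rose and 3 fell (median -0.24 and mean 0.02 against a test that pointed down, adjusted p = 0.615, but a median of 0.32 with spike-in scaling). Npas2 changed by -1.44 ± 0.16. Of 7 adipocyte markers 4 rose and 1 fell (median 0.71, adjusted p = 0.241, 0.17 with slide 2 as a term). Cfd rose by 2.87 ± 0.38 and Fabp4 by 2.84 ± 0.44 (not past the test with slide 2 as a term, 2.43). Retn rose by 1.54 ± 0.48, and its call ended with slide 2 as a term (2.21) and without intravenous cisplatin replicate 1 (1.24) or water replicate 2 (1.33). Of 12 housekeeping genes, relative to the 75th percentile, 4 rose and 1 fell (median 0.06, adjusted p = 0.359, but past the test at 0.62 with spike-in scaling, adjusted p = 0.0279, and 0.26 with quantile normalization, adjusted p = 0.0195), Gusb by 0.69 ± 0.12 (0.51 with slide 2 as a term, not past the test). Counts given once were the same adjusted over the list alone.

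In all, 8408 features were higher and 10501 lower with intravenous cisplatin, of 32215 tested (named genes 3753 and 3993), 3424 and 3781 of them by at least 2-fold. Groups did not overlap in 66.1% of features, where chance gives 10%. As each group lay on a slide of its own, slide and treatment cannot be told apart. With the slide as a random block 8531 were higher and 10631 lower. With slide 2 as a term 3574 were higher and 4501 lower, with 7712 calls shared in the same direction and 4 opposite. With spike-in scaling the median of all features moved from -0.074 to 0.49, and 84.9% of calls in place of 44.5% were higher (17052 higher, 3034 lower).

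**Figure D2:**
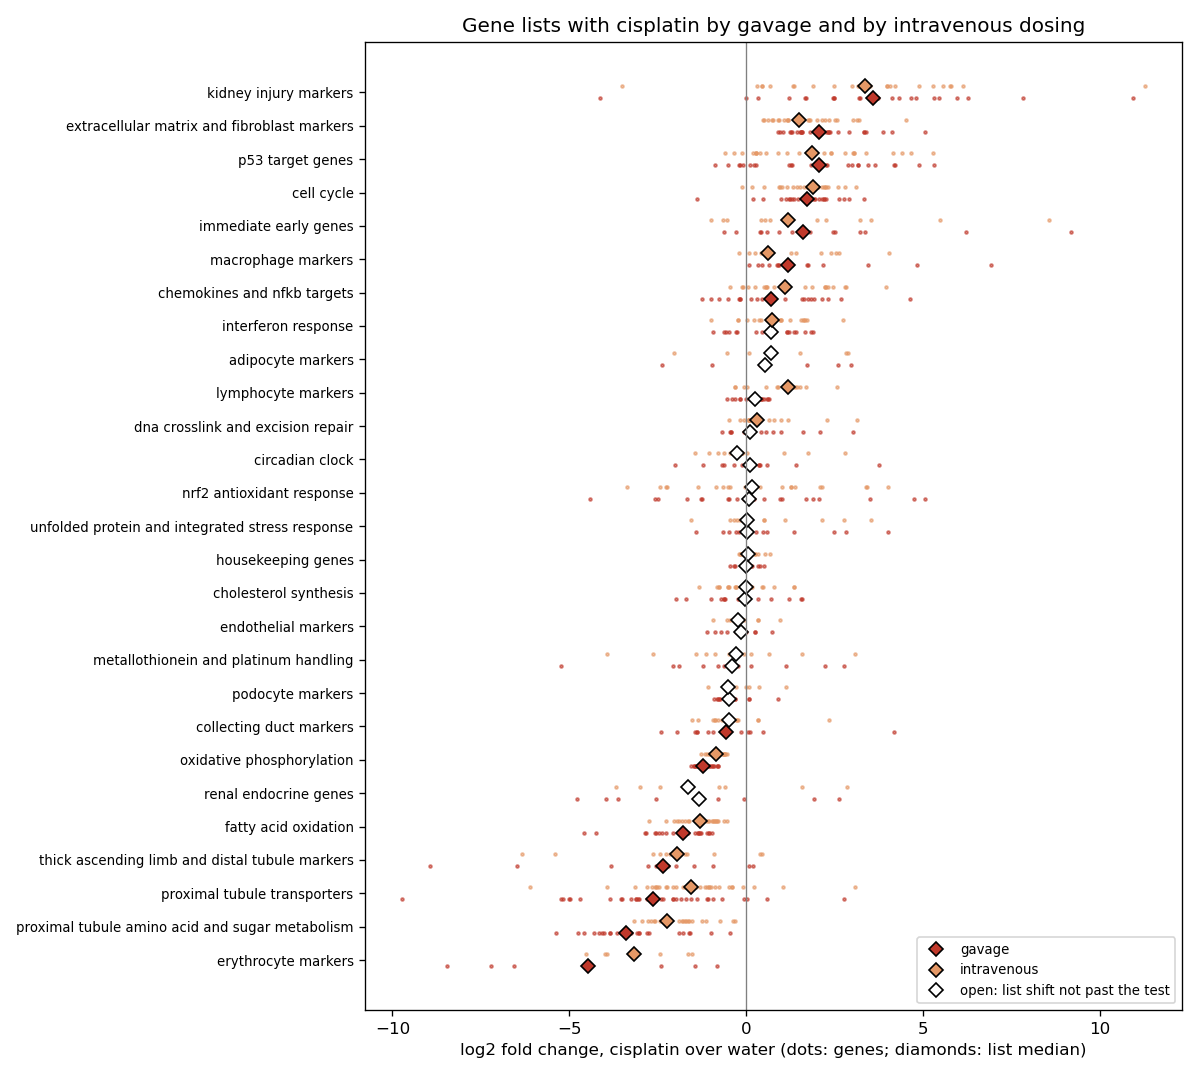
Change with cisplatin of each measured member (dots) and median (diamonds, filled where the list passed camera, open where not) of 27 gene lists, as log2 fold change on the horizontal axis, in the gavage and the intravenous experiment. Proximal tubule transporters had medians of -2.64 and -1.56 and matrix genes of 2.07 and 1.51, while the medians of collecting duct, podocyte and endothelial markers turned positive with spike-in scaling (gavage 0.11, 0.20 and 0.52, intravenous 0.08, 0.05 and 0.34), as did those of metal and platinum handling (0.26 and 0.26), cholesterol synthesis (0.63 and 0.56), housekeeping genes by gavage (0.66) and circadian genes by injection (0.32). That scaling shifts all features of an array alike, and the gavage collecting duct list still passed as lower than other genes (camera adjusted p = 0.00532).

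The experiments were then compared with each other, to see which cisplatin effects they had in common and which differed. They shared 7065 features higher and 7711 lower, against 2478 and 3167 for independent lists, and 184 features were called in opposite directions, against 5631. Across the 32215 features, which are not independent replicates, the effects correlated at r = 0.886 (Spearman 0.835), and the median ratio of the intravenous to the gavage effect was 0.786 (0.873 among those called in both, 0.783 among those called by gavage and 0.928 among those called by injection). Havcr1, Spp1, Clu, Mdm2 and Abcb1b lay among the genes higher in both and Egf, Umod, Slc22a2 and Hadh among those lower in both.

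The largest tested differences were in globins. Hbe2, Hbb-b1, Hbb, Hba-a3 and Hbb-bs changed less after injection than after gavage, with a difference (intravenous minus gavage) of 4.59 ± 0.77 for Hbe2 (n = 3 per group, limma adjusted p = 0.0410), 4.59, 4.47, 4.42 and 4.12. In the other direction the olfactory receptor Or6z5 differed by -1.64 ± 0.31, the protease Pcsk4 by -1.58 ± 0.28, the cadherin Cdh23 by -1.43 ± 0.21, the claudin Cldn23 by -1.19 ± 0.22 and Basp1 by -1.19 ± 0.23. For Cldn23 the second probe rose in both experiments, by 4.60 and 2.55, against 0.29 and -0.90 for the one that stood for it. Each of these 10 calls ended without any 1 of 10 of the 12 arrays, the exceptions being gavage and intravenous cisplatin replicate 1. Across these fits Hbe2 lay between 4.02 and 5.21 (5.21 without gavage cisplatin replicate 2). Without that array Hbb-b1 was 5.24, Hbb 5.16 and Hbb-bs 4.75, and without gavage cisplatin replicate 3 Hbb-b1 was 3.99 and Hbb 3.86. With slide 2 as a term, whose errors are wider, none of the 10 passed (adjusted p = 1.00). Hbe2 was then 4.85, no smaller than in the main fit, but Or6z5 was -0.81, Pcsk4 -0.90 and Cldn23 -0.27. Nor did any of the 10 pass with quantile normalization or spike-in scaling, and the mean of all probes gave 1.84 for Hbe2, 2.91 for Hba-a3 and -1.01 for Or6z5, not past the test. The difference of Or6z5 lay mostly between the water groups (1.502, cisplatin groups -0.13).

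Over lists, transcripts of proximal tubule transport and metabolism and of mitochondrial oxidation fell less after injection by camera. Of the 8 list differences called, 0 held with an estimated correlation and 0 by fry. The difference had a median of 0.93 (adjusted p = 1.33e-08, adjusted p = 0.534 with an estimated correlation) for proximal tubule transporters and 1.30 (adjusted p = 1.04e-08, adjusted p = 0.534 with an estimated correlation) for amino acid and sugar metabolism. It was 0.52 (adjusted p = 7.27e-10, adjusted p = 0.534 with an estimated correlation) for fatty acid oxidation and 0.34 (adjusted p = 1.07e-07, adjusted p = 0.534 with an estimated correlation) for oxidative phosphorylation. Erythrocyte markers differed by 1.75 (adjusted p = 0.0239, adjusted p = 0.534 with an estimated correlation) and lymphocyte markers by 0.73 (adjusted p = 1.64e-04, adjusted p = 0.564 with an estimated correlation). Red cell genes other than globins went both ways. Alas2 changed by -7.21 by gavage and -4.53 by injection and Slc4a1 by -2.40 and -1.53, but Ahsp by -1.45 and -2.44 and Epb42 by -0.84 and -1.64. Chemokines and NF-kB targets differed by 0.31 (adjusted p = 0.00720, adjusted p = 0.534 with an estimated correlation) and matrix genes by -0.38 (adjusted p = 0.00203, adjusted p = 0.609 with an estimated correlation). Among lists called in 1 experiment and not in the other, the test of the difference did not pass for interferon genes (0.16, adjusted p = 0.189), DNA repair genes (0.12, adjusted p = 0.187) or collecting duct markers (0.25, adjusted p = 0.0685). It did not pass either for thick ascending limb and distal tubule markers (0.31, adjusted p = 0.0685), called in both, but did with the mean of all probes (0.32, adjusted p = 0.0112), without a filter (0.33, adjusted p = 0.0373), with array weights (0.46, adjusted p = 0.00908) and with spike-in scaling (0.21, adjusted p = 0.0134). Without 1 array the distal tubule difference passed in 4 of 12 fits, the collecting duct difference in 3 and the interferon difference in 2. Single genes passed adjusted over the list alone in fatty acid oxidation (8), oxidative phosphorylation (9) and erythrocyte markers (3), against 1, 0 and 2 over all features. With slide 2 as a term the call ended for transporters (0.40, adjusted p = 0.0527), matrix (-0.35, adjusted p = 0.0527), lymphocyte (0.45, adjusted p = 0.274) and chemokine genes (0.41, adjusted p = 0.0527). It held for amino acid and sugar metabolism (0.82), fatty acid oxidation (0.42), oxidative phosphorylation (0.17) and erythrocyte markers (1.66). The erythrocyte call ended without gavage water replicate 3 (1.77) and with normexp (0.82), and the chemokine call without intravenous cisplatin replicate 2 (0.24).

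By single features, the cisplatin effect differed between the experiments for 382, of which 52 (30 named) were higher and 330 (31 named) lower after injection. The count was 0 with spike-in scaling and with quantile normalization, and 10 with slide 2 as a term. It was 2409 without gavage cisplatin replicate 1, 2153 without intravenous cisplatin replicate 1, 2 without gavage water replicate 1 and 0 in each of the other 9 of the 12 fits without 1 array.

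**Figure D3:**
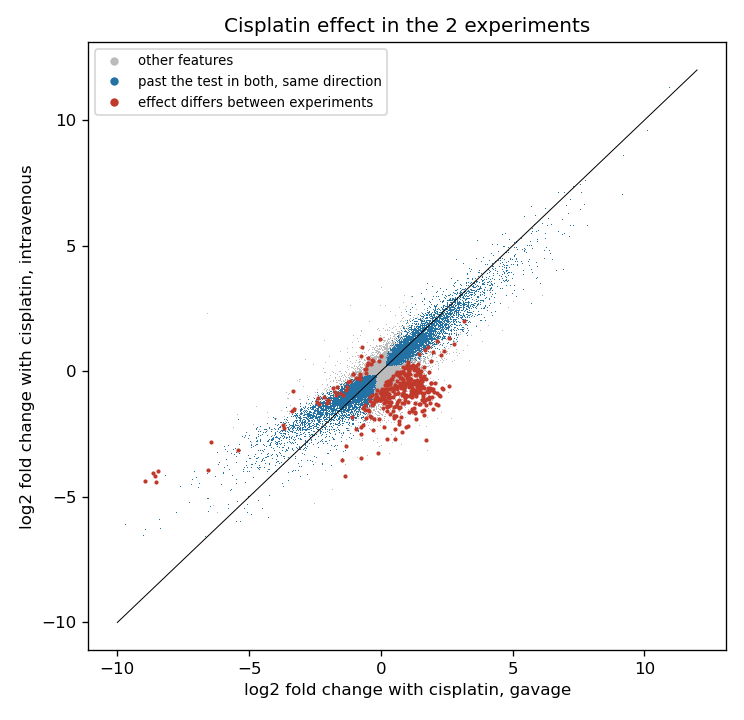
Log2 fold change with cisplatin by gavage (horizontal axis) against that by injection (vertical axis) for the tested features, with those called in both in the same direction in blue, those whose effect differed in red, all others in grey, and the line of equal change. The effects correlated at r = 0.886 across features, and 14776 features were called in the same direction in both.

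The water groups served as the background between the experiments. No gene passed between intravenous and gavage water by limma (0 of 32215, 4544 at an unadjusted p under 0.05, 28.8% of features not overlapping where chance gives 10%), and other settings called 0 to 1706. The 5 genes with the smallest p, among named genes well above background on all 6 water arrays, were Sez6 (-0.90 ± 0.11, adjusted p = 0.0632), the prolyl endopeptidase Prep (1.03 ± 0.14, adjusted p = 0.0820), the stress sensor Atf6 (-0.62 ± 0.09), Or6z5 (1.502 ± 0.22) and the arginase Arg2 (1.01 ± 0.16), none of which passed in the main fit. Among the 27 lists fatty acid oxidation was lower in the intravenous water group (-0.19, adjusted p = 0.00943, adjusted p = 0.907 with an estimated correlation). That call ended with the slide as a block (-0.11, adjusted p = 0.473), with quantile normalization (adjusted p = 0.174) and without gavage water replicate 1 or 2 (adjusted p = 0.0532 and 0.0860). Macrophage markers did not pass (0.32, adjusted p = 0.0903), but were higher in intravenous water with the slide as a block (0.44, adjusted p = 0.0239), with the 6 water arrays alone (adjusted p = 0.0486) and without gavage water replicate 3 (0.34), intravenous water replicate 1 (0.52) or gavage cisplatin replicate 3 (0.32). With the 6 water arrays alone collecting duct markers (-0.18) and oxidative phosphorylation (-0.091) were lower as well (adjusted p = 0.0461 each, 0.0903 with all 12 arrays). Injury markers (-0.01), p53 targets (-0.03) and matrix genes (0.08) had 0 members past the test, also adjusted over the list alone. Over all lists 0 members passed, and adjusted over the list alone 3 Nrf2 genes, 2 of metal and platinum handling and 1 endocrine gene were higher and 1 podocyte marker lower in intravenous water.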

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

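Chosen only after the results were seen were the tests of the red cell transcripts other than globins, of the platelet against the globin median, of slide 2, of held-out water arrays, of arrays exchanged between the experiments, of matrix against endothelial markers and of spike-in scaling, and the settings with spike-in scaling and with slide 2 as a term. No group held the 4 arrays needed to look for a single outlying sample. Errors of medians, here and under the other observations, are taken over genes or features as if independent and hold no spread between animals.

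Globin and red cell transcripts fell in both experiments, with a median of -8.57 by gavage and -4.12 by injection over 6 globin genes, and they drew attention because the cisplatin effect differed between the experiments. The difference (intravenous minus gavage) was 4.59 for Hbe2, 4.59 for Hbb-b1, 4.47 for Hbb, 4.42 for Hba-a3, 4.12 for Hbb-bs, 2.64 for Hba-a1 and 1.75 over the erythrocyte list, a list call that ended with an estimated correlation (adjusted p = 0.534), by fry (adjusted p = 0.135) and without gavage water replicate 3 (adjusted p = 0.171), single globins being uncertain because of paralogs. The platelet median lay above the globin median by 7.64 ± 0.69 in the gavage experiment. This gap cannot decide on less blood left in the cortex as the whole cause, because dim platelet markers could not fall as far as the globins. In gavage water these markers stood between -5.39 (Ppbp) and -0.39 (Pf4, which rose by 1.41). The lowest signal well above background was 19.1 to 23.4 on gavage cisplatin arrays, against a 75th percentile of 1439 to 1532. Whether less blood took part is not decided either, because the platelet median of -0.93 ± 0.53 lay within its error of the -1 set as the bound. Of the 7 platelet markers 4 were called lower, 1 higher and 2 did not pass. Fewer young red cells may have contributed, but the median of 9 other erythroid genes (-1.45 ± 1.12) was too spread to decide. A true difference between routes, doses or experiments stays open and untested, as blood counts were not used here.

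The second pattern is the 330 features with a lower and the 52 with a higher cisplatin effect after injection than after gavage. Among those lower, gavage cisplatin replicates 2 and 3, on slide 2, lay above replicate 1, on slide 1, by a median of 0.61 ± 0.037, in 92.7% of features against 48.4% of all features, while among those higher the gap was -0.14 ± 0.043, above 0 in 21.2%. A true difference of response to cisplatin as the whole cause, with water groups alike, is argued against by water arrays left out of the choice: over as many features chosen without 1 water array of each experiment, the intravenous one lay above the gavage one by a median of 0.72, 0.62 and 0.54 ± 0.044, against -0.02, 0.003 and -0.03 over all features, so a reading of slide 2 that is higher for the 330 may account for them, while a difference between the water animals stays open, as all intravenous water arrays lay on slide 2 and all gavage water arrays on slide 1. Among 100 ways to exchange arrays between the experiments within cisplatin and within water, 2 called as many features as the real 382, itself included. That share is under 0.05, but the test was chosen after the data were seen, and it excludes neither chance nor the slide. The highest other (1014) exchanged gavage with intravenous cisplatin replicate 1, kept both cisplatin arrays of slide 2 in 1 group and points to a structure of the samples. Of 100 assignments of cisplatin and water within the experiments 8 called as many (highest other 11631), which decides nothing, because 65 of them left part of the cisplatin effect in the difference.

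The third pattern is that proximal and distal tubule transcripts fell while matrix and macrophage transcripts rose, list calls that ended with an estimated correlation (adjusted p = 0.263 to 0.440). A lower share of tubule cells as the whole cause would raise the markers of other cell types alike. The matrix median exceeded the endothelial median by 2.21 ± 0.31 by gavage and 1.73 ± 0.29 by injection. These errors treat the genes of a list as independent and hold no spread between animals, so they may be too small to decide. Scaling on the 75th percentile as the cause is argued against by the transporter median of -1.97 ± 0.44 in the gavage experiment with spike-in scaling. A loss of tubule cells together with growth of matrix cells, or a change of transcription within cells, could each give the pattern, and bulk RNA leaves both open.

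Other results were singled out because the effect of cisplatin, tested as a difference of the experiments (intravenous minus gavage), was unequal. Among genes the difference was -1.64 for Or6z5, -1.58 for Pcsk4, -1.43 for Cdh23, -1.19 for Cldn23, -1.19 for Basp1, 1.06 for Sez6, 0.66 for Atf6, 0.49 for Etfa and 0.65 for Ugdh. For Or6z5, Sez6 and Atf6 it lay mostly between the water groups (1.502, -0.90 and -0.62, intravenous minus gavage, none past the test), the cisplatin groups differing by -0.13, 0.16 and 0.04. The water groups also held the larger part for Cldn23 (0.67, cisplatin groups -0.52) and Basp1 (0.62 and -0.57). The cisplatin groups held the larger part for Pcsk4 (-0.81, water groups 0.76), Cdh23 (-0.84 and 0.59), Etfa (0.25 and -0.24) and Ugdh (0.44 and -0.21). Over lists it was 0.93 for proximal tubule transporters, 1.30 for amino acid and sugar metabolism, 0.52 for fatty acid oxidation, 0.34 for oxidative phosphorylation, -0.38 for matrix genes, 0.73 for lymphocyte markers and 0.31 for chemokines and NF-kB targets. None of these list calls held with an estimated correlation (adjusted p = 0.534 to 0.609) or by fry, and those of transporters, matrix, lymphocyte and chemokine genes ended with slide 2 as a term. The E1A control spots, which entered the comparisons of genes only through spike-in scaling, showed a signal of their own: relative to the E1A spike-ins the 75th percentile of cisplatin arrays lay above that of water arrays by 0.67 by gavage (-3.53 ± 0.18 against -4.20 ± 0.03, mean ± SD, n = 3) and by 0.56 by injection (-3.47 ± 0.05 against -4.03 ± 0.11).

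The 10 splits of 6 arrays into groups of 3 are too few for a share under 0.05. In the gavage experiment 1 of 10 splits called as many features as the real 19211 (highest other 0), in the intravenous experiment 1 of 10 as many as the real 18909 (highest other 1), and between the water groups 10 of 10 as many as the real 0 (highest other 2).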

How the results depend on the processing

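Spike-in scaling and slide 2 as a term were chosen after seeing the data. Slide 2 as a term also widens the errors by injection, because its slide effect rests on the gavage cisplatin arrays alone. Of 122 genes named by rule and called by gavage 115 kept direction and call under every alternative fixed in advance, 120 under every omission of 1 array and 110 under both added settings, and of 125 called by injection 120, 123 and 88. Of the 14 and 16 lists called, 12 and 15 kept their call under the alternatives fixed in advance, 13 and 16 without any 1 array and 12 and 13 under the added settings. With an estimated correlation only the injury list of the intravenous experiment held its call (0 of 14 lists by gavage, 1 of 16 by injection, 0 of 8 for the difference, 0 of 1 between water groups). By fry, 14 of 14, 16 of 16, 0 of 8 and 0 of 1 passed. Fry also called lists that camera did not, 23 lists in all by gavage and 24 by injection. As fry does not compare a list with other genes, and 59.6% and 58.7% of all features were called, its passes do not bear out the camera calls.

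Spike-in scaling gave 20049 higher and 3103 lower features by gavage, 17052 and 3034 by injection and 0 whose effect differed. Slide 2 as a term gave 3574 and 4501 by injection, 6972 in the same direction in both experiments, 10 for the difference and 6 between water groups. A change of at least 2-fold left 4306 and 3757, 3424 and 3781, and 5439 in both. The difference called 0 features with quantile normalization, without a filter, with the replicate block and at an adjusted p under 0.01, 593 with all 12 arrays well above background and with the slide as a random block, and 2264 with array weights. Between water groups 8 were called with normexp, 4 with all 12 arrays well above background, 922 with 6 arrays alone, 1706 with array weights, 1 with a trended robust prior and 6 with the slide as a fixed block. Fewer features tested lowers the number of adjustments and a 2-fold threshold removes small changes; for the other settings the cause was not tested.

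Values that changed sign were Ppia by gavage (0.22 with quantile normalization, 0.33 with spike-in scaling) and Cdkn1a, whose mean of all probes was 3.82 by gavage and 3.59 by injection (0.47 by gavage with spike-in scaling), because its probes differ. With spike-in scaling Nphs1 was 0.13, Slc30a1 0.046, Clock 0.052 and Gapdh 0.22 by gavage, and Clic5 0.025, Podxl 0.010, Ehd3 0.10 and Tie1 0.18 by injection, as this scaling adds one shift per array. Among genes named only after their values were seen it gave 0.16 for Xpc, 0.15 for Il34, 0.053 for Fosb, 0.21 for Xpa, 0.23 for Fancl, 0.0038 for Dnajb9 and 0.18 for Hspa5 by gavage, and 0.12 for Cx3cl1, 0.070 for Fancc, 0.024 for Egr3, 0.11 for Dnajb9 and 0.21 for Chac1 by injection, and the mean of all probes gave 1.49 for Chac1 by injection. Among 6615 genes with several tested probes, 1.57% (104) by gavage and 2.43% (161) by injection had probes called in opposite directions.

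Without 1 array the counts ranged from 8489 to 9787 higher and 8690 to 9898 lower by gavage, 7444 to 8416 and 9194 to 10726 by injection, 13269 to 14439 in both, 0 to 2409 for the difference (2409 without gavage cisplatin replicate 1, 2153 without intravenous cisplatin replicate 1) and 0 to 1108 between water groups (1108 without gavage cisplatin replicate 1). The cell cycle list's difference ranged from -0.29 (without intravenous cisplatin replicate 2, adjusted p = 0.0439) to 0.24. The replicate number did not pair the animals: of 18 pairs with the same number 1 correlated over 0.1 (r = -0.35 to 0.18). With it as a block 9278 and 9420 features were called by gavage, 8155 and 10155 by injection, 14236 in both, 0 for the difference and 0 between water groups, and the erythrocyte list's difference (1.75) did not pass (adjusted p = 0.0532).

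Genes not well above background in a group carry only bounds of their fold, and 3 arrays per group limit what small changes can be called.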

Other observations

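Markers of other blood cells stood outside the lists of the comparisons. Of 7 platelet markers measured 4 fell, 1 rose and 2 did not pass by gavage, with the receptor subunits Gp9 and Gp1bb at -1.64 and -1.35, Clec1b at -1.75 and the platelet chemokine Pf4 up by 1.41, and by injection 3 fell, 1 rose and 3 did not pass (median -0.54 ± 0.41). Of 5 neutrophil markers 1 fell by gavage (Retnlg, -1.64, not past the test at -1.30 without cisplatin replicate 3, -1.81 with the slide as a block or -0.98 with spike-in scaling) and 4 did not pass (median -0.94 ± 0.37), and 0 of 5 passed by injection (limma, median -0.60 ± 0.24). The calgranulins S100a8 and S100a9 gave -0.94 and -1.04 by gavage and -0.92 and -1.03 by injection, with 0 of these passing. Without gavage cisplatin replicate 3 S100a8 (-1.60) and S100a9 (-1.62) passed by gavage and S100a9 by injection (-1.03), and the last also without intravenous cisplatin replicate 2 (-1.43). Of 9 erythroid genes other than globins, 4 of which also stand in the erythrocyte list, 4 fell, 1 rose and 4 did not pass by gavage and 5 fell, 1 rose and 3 did not pass by injection (median -1.64 ± 0.81). Rhd, a red cell antigen, changed by -1.96 and -2.39 (-2.16 with slide 2 as a term, not past the test).

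Of 7 adrenal cortex markers 2 were measured, and they moved apart. Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, rose by 4.35 ± 0.64 by gavage (water arrays well above background on 1 of 3, 5.12 without gavage water replicate 1) and at least 7.57-fold by injection, where its call ended with slide 2 as a term (2.42). Cyp21a1, the steroid 21-hydroxylase, changed by -0.71 ± 0.19 and -1.38 ± 0.19, the first not past the test with spike-in scaling (-0.043, adjusted p = 0.866). The call of a gene could depend on the probe that stood for it. In 169 genes by gavage and 178 by injection that probe was not called, or was called the other way, beside another probe called with at least a 2-fold change.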
